A study of Mus musculus with 53 samples.

How the data were processed

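Total RNA of NIH-3T3 cells with an empty vector, PPARg2 or EBF1 was hybridised to 53 Affymetrix MG_U74Av2 arrays. The deposited table gives 1 intensity for each of 12488 probe sets on each array, on a linear scale, as the authors computed it. Which algorithm summarised the probes and how the arrays were scaled is not given in the sources used here. The table itself showed some scaling: array means ran from 309 to 370, and 46.8% to 51.9% of the probe sets of an array lay above the pooled median. No further scaling was applied. The arrays' 20th percentiles ran from 47.8 to 60.3, and the 3' to 5' ratio of actin signals from 1.06 to 1.59. Array experiment files were read only for the session in which each array was processed, and 3 sessions were told apart.

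Groups were taken from the sample titles as insert by day, which made 12 groups. Values below the pooled 20th percentile (54.5, or 5.77 on the log2 scale) were set to that floor, and log2 was taken. The 66 control probe sets were left out, and 7619 probe sets above the pooled median of 158 on at least 2 arrays were tested. Gene symbols came from the platform annotation: 10833 probe sets had 1 symbol, of which 10817 were checked through the Entrez identifier, 396 had several symbols and 1193 had none. Each of 5761 genes was represented by the probe set with the highest mean log2 intensity over all arrays.

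Differences were computed with limma 3.58.1 in R 4.3.3, in 1 model with a mean for each of the 12 groups over all 53 arrays, moderated with an intensity trend, and adjusted by Benjamini-Hochberg over the probe sets within each comparison, with a threshold of 0.05. There were 19 comparisons: each pair of inserts on each day, vector d2, d4 and d10 against d0, d10 against d0 within each insert group, and, for both inserts, the difference from vector at d10 against that at d0. A count adjusted over the list alone (list-wise) used the same p values adjusted within the list. Where a whole group was at the floor, the fold was given as a lower limit. The wording "passed" refers to this test.

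For gene groups, 20 lists were fixed before the data were examined, from general knowledge of adipocyte, fibroblast and other cell biology, and 19 of them with at least 5 tested genes were tested against all other genes with camera at a preset correlation of 0.01 and again with an estimated one. The list of brown fat genes had 3 tested genes and is given as values. Some genes stand in several lists, such as 7 of the 35 adipocyte markers. The adipocyte score is the mean over 28 adipocyte markers with a probe set (Pparg left out, since it was an insert) of the log2 distance from the mean of the vector arrays at d0. It was tested by exact permutation of the arrays of the groups compared, two-sided, and adjusted over 12 comparisons.

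The genes named were chosen by a rule written before the data were examined. It took, of the genes past the test and without overlap between the groups' arrays, the 5 largest rises and falls in the comparisons of each insert with vector at d4 and d10, and the 3 largest elsewhere. No overlap was asked for the differences between d10 and d0 effects. It also took Pparg and Ebf1, the panel Fabp4, Adipoq, Cfd, Lpl, Cd36, Cebpa, Cebpb, Cebpd, Lep and Dlk1, and per list the 3 or, outside the main comparisons, 2 genes with the largest folds past the test. Not every gene that the rule allows is printed.

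The similarity of the inserts' effects was measured by Pearson's r and the covariance over genes, beside 100 draws in which residuals of all arrays were dealt to groups that share their controls. A first version drew only from the arrays of the same day, which mirrored residuals in the smallest group, and it was replaced by draws from all groups of at least 3 arrays after its values were seen. The division of the 3 vector arrays of d10 between the inserts was also added after the data were seen. Replicate numbers were tested as pairs, and the arrays were not treated as paired.

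The procedure was tested on simulated data with normal noise of each probe set's own spread, in which 67 probe sets were changed by a log2 of 0.5, 67 by 1 and 66 by 2. A log2 change of 1 was found for 100% of changed probe sets in PPARg and 98.5% in EBF1 against vector at d4. At d10 these were 95.5% and 82.1%, and 76.1% in the difference of EBF1 effects. A change of 0.5 gave 80.6%, 86.6%, 47.8%, 35.8% and 13.4%. Camera found each of 19 lists shifted by 0.5 in turn and called 0 others, but correlated genes were not simulated.

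Alternatives were quantile normalization, a floor at the 40th percentile (115), no filter, a strict filter (above the 60th percentile, 215, on at least 4 arrays), a fit of only the groups compared, array weights, replicate number as a block, session as a block and each session alone, leaving out each array in turn and, for the score, the mean of all probe sets of a gene. The estimation of array weights stopped before it converged and gave PPARg replicate 2 of d10 a weight of 53.2. For this reason weights estimated gene by gene were added after the data were seen, as was a fit with each array's 20th percentile as a covariate. No array and no column of the table was left out.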

Results

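Expression was measured in NIH-3T3 cells, an immortalised line of mouse embryonic fibroblasts, that carried an empty vector, a vector for PPARg2, the adipocyte form of the nuclear receptor Pparg, or a vector for EBF1, a transcription factor first known from B lymphocytes. The cells were given hormones that start adipocyte differentiation, and total RNA was taken on days 0, 2, 4 and 10 (d0, d2, d4 and d10). Each RNA was hybridised to an Affymetrix MG_U74Av2 array, and the deposited table held 1 linear intensity for each of 12488 probe sets on each of 53 arrays. There were 4 arrays per insert at d0 and at d2, 7 at d4, and 3 vector, 3 PPARg and 2 EBF1 arrays at d10, so that the number of arrays limited the precision, most of all at d10. The labels call the stimulations independent, and nothing else says which arrays came from separate cultures. Arrays of 1 group differed unequally, with a mean absolute log2 difference of 0.094 to 0.396 between pairs of the vector arrays of d0 and 0.097 to 0.312 between those of PPARg at d10. Repeat hybridisations of 1 RNA are therefore not excluded, and n counts arrays. The array medians lay between 143 and 168, the pooled 20th percentile of 54.5 served as the floor, and 7619 probe sets (5761 genes) were tested. The arrays had been processed in 3 sessions: sessions 1 and 2 each held 2 arrays of every group of d0, d2 and d4, and session 3 held 3 arrays per insert of d4 and all arrays of d10. The d0 and d10 arrays therefore shared no session, and comparisons between these days were tied only through d4. Values after ± are standard errors of log2 folds unless SD is written, and p values are two-sided. Genes said to rise or fall most, or with the largest rises or falls, lead the genes past the test whose arrays do not overlap between the groups; genes given for a list or panel needed no such gap.

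The gene carried by each vector was examined first. The Pparg probe set (Entrez 19016) was at or below the floor on all 4 vector arrays and all 4 EBF1 arrays of d0. The 4 PPARg arrays of d0 gave a mean intensity of 69.1 ± 14.2 (SD). At d4 the mean Pparg intensity was 84.7 ± 8.68 (SD, n = 7) with vector, 218 ± 57.4 with PPARg and 208 ± 51.7 with EBF1. At d10 Pparg was at the floor again on all 3 vector arrays, and stood at 199 ± 32.7 (SD, n = 3) with PPARg and 221 ± 44.7 (SD, n = 2) with EBF1. The Ebf1 probe set (Entrez 13591) did not pass the test in EBF1 arrays on any day, with log2 folds over vector of 0.14 ± 0.17 at d0, 0.17 ± 0.17 at d2, 0.11 ± 0.13 at d4 and -0.14 ± 0.22 at d10. Replicate 3 of the vector group at d0 lay above the other 3 arrays for Ebf1. Whether either probe set lies inside the sequence that the vectors carried is not known from the sources used here, so these values do not check the inserts.

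Adipocyte markers address how far and fast cells with each insert differentiated. Adipoq, the secreted adipocyte hormone adiponectin (Entrez 11450), was near the floor in every group at d0, with 10 of 12 arrays at or below it. At d4 its mean intensity was 964 ± 184 (SD, n = 7) with vector, 2360 ± 346 with PPARg and 3975 ± 566 with EBF1. At d10 it was 880 ± 534 (SD, n = 3) with vector, 6427 ± 207 with PPARg and 7699 ± 466 (n = 2) with EBF1. Lpl, the lipase that frees fatty acids from lipoproteins (Entrez 16956), reached 2235 ± 491 (SD) at d10 with vector, 5895 ± 88.6 with PPARg and 7728 ± 1300 with EBF1. Fabp4, the fatty acid carrier of adipocytes (Entrez 11770), was at the floor on all 12 arrays of d0 and gave 78.9 ± 44.8 (SD) at d10 with vector, where 1 of 3 arrays was at the floor, 574 ± 141 with PPARg and 885 ± 365 with EBF1. Cd36, a fatty acid transporter, Cebpa, a late adipogenic transcription factor, and Lep, leptin, passed with neither insert at d4 or d10. Their log2 folds over vector at d10 ran from 0.10 ± 0.23 (Cebpa, PPARg) to 0.68 ± 0.25 (Cd36, EBF1). Cd36 and Cebpa group means lay below the filter of 158 and Lep already read 583 in vector d0, which limits these tests. Another Lep probe set rose with PPARg at d10. Cfd has no named probe set and was not analysed. EBF1 replicate 7 of d4 lay below the other 6 for Adipoq and Lpl.

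The mean log2 distance of 28 adipocyte markers from the vector arrays of d0, here called the adipocyte score, gathered these genes on each array. With vector it was 0.48 ± 0.05 (SD, n = 4) at d2, 1.16 ± 0.10 (n = 7) at d4 and 0.62 ± 0.21 (n = 3) at d10. With PPARg it was 0.17 ± 0.05 (SD, n = 4) at d0, 0.73 ± 0.08 at d2, 1.55 ± 0.07 (n = 7) at d4 and 2.14 ± 0.11 (n = 3) at d10. With EBF1 it was 0.11 ± 0.07 (SD, n = 4) at d0, 0.43 ± 0.10 at d2, 1.55 ± 0.12 (n = 7) at d4 and 2.15 ± 0.11 (n = 2) at d10. At d4 both inserts lay above vector by 0.39, and every PPARg and EBF1 array exceeded every vector array (exact permutation p = 5.8e-04 for each, adjusted p = 0.0035 over 12 comparisons). The within-session differences at d4 were 0.29, 0.38 and 0.45 for PPARg and 0.36, 0.43 and 0.38 for EBF1 in sessions 1, 2 and 3. At d2 PPARg lay above vector by 0.25 and EBF1 lay below PPARg by 0.30, without overlap, but neither passed after adjustment (exact permutation p = 0.029 for each, adjusted p = 0.086). Those differences were 0.30 and 0.21 for PPARg over vector, and -0.36 and -0.25 for EBF1 minus PPARg, within sessions 1 and 2. The d10 differences from vector, 1.52 for PPARg and 1.53 for EBF1, had all insert arrays above all vector arrays, yet 0.1 is the smallest p that the exact permutation test can reach there (adjusted p = 0.17). EBF1 minus PPARg was 0.0032 at d4 (exact permutation p = 0.95) and 0.0086 at d10 (exact permutation p = 1). At d0 PPARg lay above vector by 0.17 (exact permutation p = 0.057) and EBF1 by 0.11 (exact permutation p = 0.17), and at d2 EBF1 lay below vector by 0.05 (exact permutation p = 0.49). Replicate 7 of the EBF1 group at d4 had the lowest score of its group, 1.31, against 1.53 to 1.64 for the other 6.

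**Figure D1:**
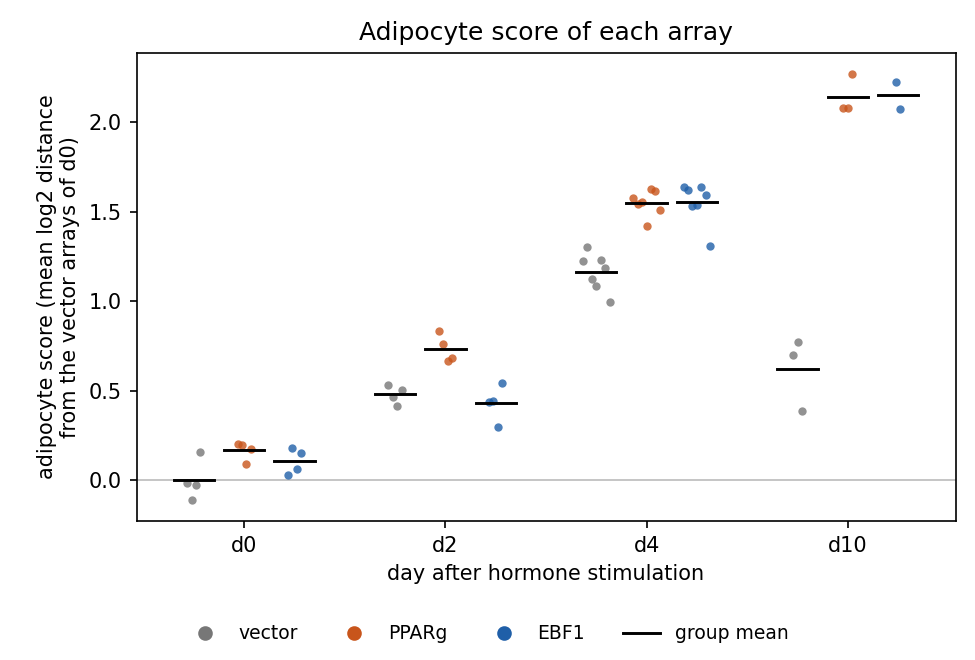
Adipocyte score (mean log2 distance of 28 markers from the vector arrays of d0) on each of 53 arrays, by day and insert, with group means as bars. At d10 the PPARg and EBF1 arrays stood between 2.08 and 2.27, and the vector arrays between 0.38 and 0.77.

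**Figure D2:**
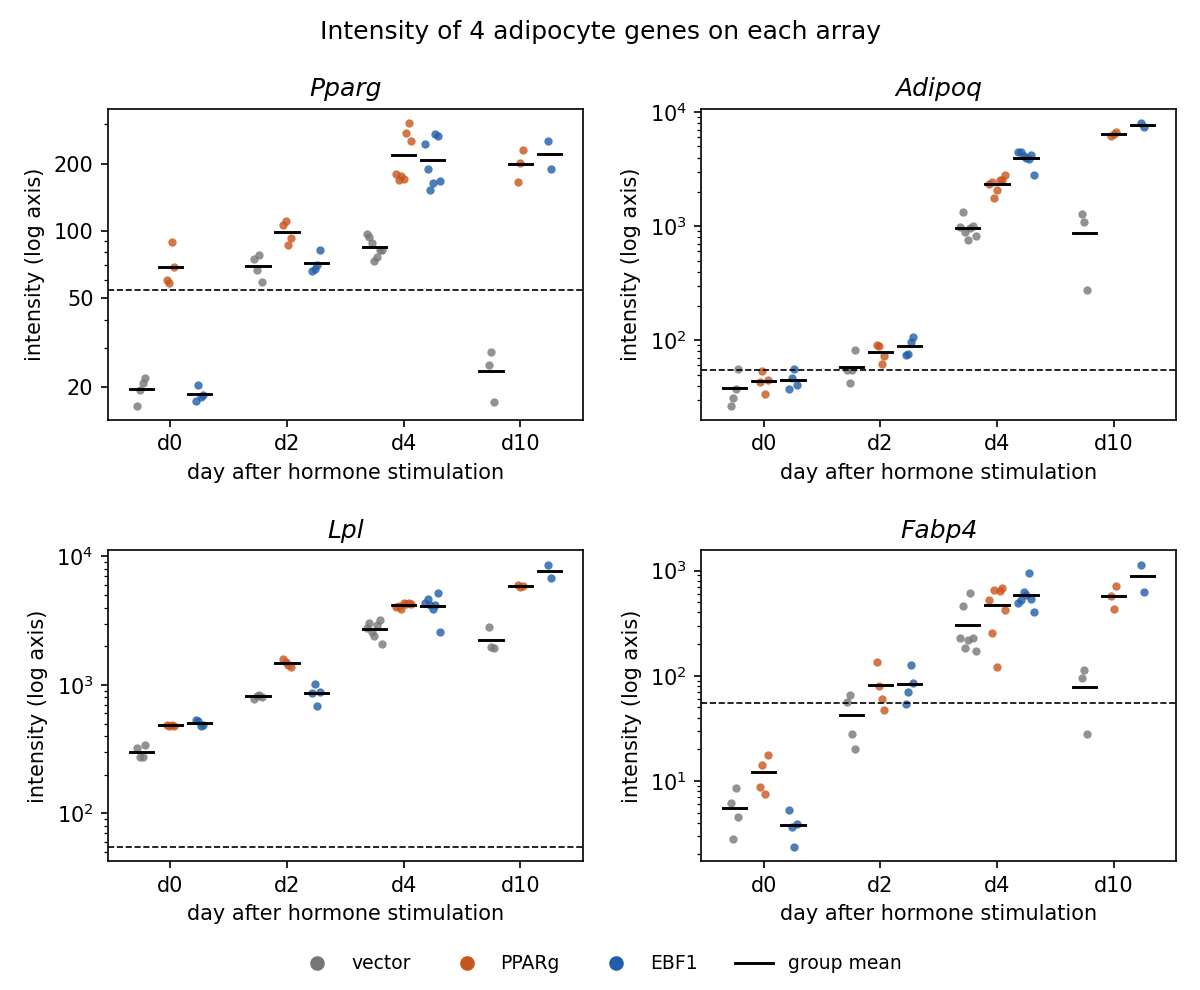
Intensity (log axis) of Pparg, Adipoq, Lpl and Fabp4 on each array, by day and insert, with the floor of 54.5 as a dashed line. Adipoq averaged 880 with vector, 6427 with PPARg and 7699 with EBF1 at d10.

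The vector arrays of d2 (n = 4) against those of d0 (n = 4) show the hormone response without an insert. The largest rises were in the acute phase genes Saa3 (log2 fold 6.85 ± 0.30), Lcn2 (4.57 ± 0.44) and Saa2 (3.57 ± 0.33). The largest falls were in Crabp1, a retinoic acid binding protein (-4.12 ± 0.15), and in Fdps (-3.95 ± 0.28) and Idi1 (-3.93 ± 0.20) of isoprenoid synthesis. Of 17 glucocorticoid and cAMP response genes tested 13 rose and 1 fell (the same counts adjusted over the list alone, or list-wise), among them Angptl4, a lipase inhibitor (2.51 ± 0.15). All 12 cholesterol synthesis genes fell, also when list-wise. Of 18 cytokine, chemokine and acute phase genes 11 rose while 2 fell (11 and 3 list-wise). Among adipocyte markers 9 of 27 rose (9 list-wise), including Lpl (1.43 ± 0.13) and Agt, the precursor of angiotensin (2.51 ± 0.16). The early adipogenic transcription factors Cebpb (1.13 ± 0.19) and Cebpd (1.46 ± 0.19) rose, and Dlk1, a marker of preadipocytes, fell (-0.68 ± 0.15). Of 19 actin and smooth muscle genes 10 fell and 1 rose (12 and 1 list-wise), among them Acta2, smooth muscle actin, which fell at least 5.75-fold and was at the floor on all 4 arrays of d2. Of 29 cell cycle genes 12 fell and 2 rose (the same list-wise), with Mki67, a marker of proliferation, at -1.33 ± 0.20 and Top2a, a topoisomerase of dividing cells, at 2.83 ± 0.19. In all 679 probe sets were higher and 956 lower. Camera called 10 lists, 6 of them under both correlations. The calls for glucocorticoid response (adjusted p = 7.1e-14), cholesterol synthesis (4.4e-24), cytokines (1.4e-06), adipocyte markers (6.5e-06) and actin genes (5.2e-05) held with an estimated correlation, and that for the cell cycle was lost (adjusted p = 0.63 with an estimated correlation). Holding or being lost refers to the estimated correlation throughout. With session as a block 1944 probe sets changed, and 1866 and 722 changed within sessions 1 and 2, where the mean log2 fold of the adipocyte markers was 0.59 and 0.43 against 0.51 pooled. Further probe sets of Saa2, Fdps, Angptl4 and Lpl did not pass the test.

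By d4 the vector arrays (n = 7) had moved further from d0 (n = 4) in adipocyte genes. Saa3 (log2 fold 5.47 ± 0.27), Adipoq (4.12 ± 0.20, with 3 of 4 arrays of d0 at the floor) and Agt (3.73 ± 0.14) rose most. Crabp1 (-3.57 ± 0.13), the growth arrest gene Gas2 (-3.19 ± 0.11, with 6 of 7 arrays of d4 at the floor) and Idi1 (-3.18 ± 0.18) fell most. Among 27 adipocyte markers 17 rose (17 adjusted over the list alone), with Lpl at 3.15 ± 0.11, and Fabp4 rose at least 4.93-fold and Pparg at least 1.55-fold. Of 22 genes of fatty acid oxidation and peroxisomes 18 rose and 1 fell (20 and 1 list-wise), such as Acadm, which opens the oxidation of medium-chain acids (2.09 ± 0.11). Glucocorticoid and cAMP response genes rose in 13 of 17 cases (13 list-wise), with Fkbp5, a glucocorticoid target, at 2.44 ± 0.09, and all 12 cholesterol synthesis genes stayed below d0 (12 list-wise). Cebpb (0.98 ± 0.17) and Cebpd (0.98 ± 0.16) were still raised, and Dlk1 was at -0.34 ± 0.13, not past the test. Counted over all probe sets 863 were higher and 977 lower. Camera called 9 lists, 4 of them under both correlations, among them the adipocyte markers (adjusted p = 2.4e-19), the glucocorticoid response (3.1e-16) and cholesterol synthesis (1.4e-21), and fatty acid oxidation only with the preset correlation (adjusted p = 4.0e-10, and adjusted p = 0.11 with an estimated correlation). A session block gave 1926 changed probe sets, and sessions 1 and 2 alone gave 2478 (936 higher) and 645 (418 higher), with mean log2 folds of the adipocyte markers of 1.39 and 1.10 against 1.23 pooled.

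On d10 the vector arrays (n = 3) kept part of this change against d0 (n = 4). Adipoq (log2 fold 3.72 ± 0.25), the growth factor Igf2 (3.46 ± 0.38) and Clec3b, the plasminogen binding protein tetranectin (3.30 ± 0.21), rose most. Idi1 (-3.19 ± 0.22), Fdps (-2.92 ± 0.30) and Ccn2, a matricellular growth factor (-2.64 ± 0.15), fell most. Of the 27 adipocyte markers 11 rose (11 adjusted over the list alone), with Lpl at 2.87 ± 0.14, and Fabp4 did not pass (0.62 ± 0.39). Cebpd was below d0 (-0.68 ± 0.20), Cebpb did not pass (-0.56 ± 0.21) and Dlk1 was above d0 (0.66 ± 0.16). Of 34 preadipocyte and fibroblast matrix genes 14 rose and 3 fell (18 and 4 list-wise), such as Eln, the elastic fibre protein (2.97 ± 0.20). Among 18 cytokine genes 8 rose (10 rose and 1 fell list-wise), including the chemokine Cxcl12 (1.89 ± 0.21). All 12 cholesterol synthesis genes fell (12 list-wise), and 10 of 29 cell cycle genes fell while 1 rose (11 and 1 list-wise). There were 726 probe sets higher and 446 lower, a share of 61.9% higher that became 51.7% (679 and 634) with quantile scaling. Of 9 lists that camera called, 3 held under both correlations, cholesterol synthesis (adjusted p = 3.4e-33), cytokines (5.3e-07) and adipocyte markers (8.7e-07), but matrix genes (adjusted p = 2.1e-05) and the cell cycle (7.8e-04) were lost (adjusted p = 0.12 and adjusted p = 0.30). A session block, tied through d4 alone, gave 711 changed probe sets.

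PPARg against vector at d0 (n = 4 each) asks what PPARg2 changed before hormones were added. Egr1, an immediate early transcription factor (log2 fold 1.59 ± 0.41), Angptl4 (1.29 ± 0.15) and Dusp6, a phosphatase of ERK kinases (1.25 ± 0.22), rose most. Cxcl12 (-1.93 ± 0.19), the collagen binding proteoglycan Lum (-1.46 ± 0.30) and the basement membrane protein Nid2 (-1.45 ± 0.27) fell most. Among 27 adipocyte markers 3 rose and 1 fell (4 and 1 adjusted over the list alone), among them Plin4, a lipid droplet protein (0.77 ± 0.18), and Lpl (0.68 ± 0.13). Among 29 cell cycle genes 19 rose (23 list-wise), with the survivin gene Birc5 at 1.03 ± 0.14. Of 34 matrix genes 4 fell and 1 rose (5 and 1 list-wise), including Dcn, the proteoglycan decorin (-0.99 ± 0.12). Rises were found in 4 of 20 unfolded protein and amino acid stress genes (8 rose and 1 fell list-wise), 3 of 19 glycolysis and hypoxia genes (7 list-wise) and 4 of 17 glucocorticoid and cAMP genes (6 list-wise). Pparg read 58.3 to 89.3 with PPARg and 16.5 to 21.8 with vector. As vector was set to the floor, the test (at least 1.25-fold, adjusted p = 0.48) cannot judge this. Altogether 159 probe sets were higher and 115 lower, a share of 58.0% higher that became 47.5% (155 and 171) with quantile scaling and 40.4% (116 and 171) without vector replicate 4. The count of 274 was 115 in a fit of these groups alone and 4866 with array weights. Of 7 camera calls that for the cell cycle (adjusted p = 2.9e-32) alone held, and those for adipocyte markers, matrix, stress, glycolysis and glucocorticoid genes were lost (adjusted p = 0.47, 0.29, 0.29, 0.34 and 0.15). With session as a block 442 probe sets changed, and within sessions 1 and 2 there were 527 (167 higher and 360 lower) and 125 (102 and 23), with mean log2 marker folds of 0.27 and 0.10 against 0.19 pooled. Further probe sets of Angptl4 and Lpl did not pass.

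EBF1 against vector at d0 (n = 4 each) asks the same of EBF1. Igf2 (log2 fold 2.30 ± 0.35), the matrix protein periostin, Postn (1.61 ± 0.17), and Sparcl1, a matricellular protein (1.28 ± 0.20), rose most without overlap. Ccn2 (-1.34 ± 0.14), the glypican Gpc4 (-1.15 ± 0.18) and the caveolar protein Cavin2 (-1.07 ± 0.18) fell most. Lpl (0.74 ± 0.13) and Angptl4 (0.60 ± 0.15) were the 2 adipocyte markers of 27 that rose (2 adjusted over the list alone). Of 18 cytokine genes 3 rose (4 list-wise), among them the chemokine Ccl2 (1.32 ± 0.29), and the metallothionein Mt2 rose among glucocorticoid targets (0.68 ± 0.10). None of 12 cholesterol synthesis, 20 stress and 23 citrate cycle genes passed singly, with mean log2 folds of -0.19, -0.19 and -0.08. In total 30 probe sets were higher and 32 lower, 62 against 31 in a fit of these groups alone and 2801 with array weights. Camera called 4 lists, cytokines, cholesterol synthesis (adjusted p = 1.9e-04 for each), stress genes (8.9e-07) and citrate cycle genes (0.033), and all were lost (adjusted p = 0.12, 0.22, 0.077 and 0.68). A block for session gave 102 changed probe sets, and sessions 1 and 2 gave 119 (34 higher) and 19 (14 higher), with mean log2 marker folds of 0.17 and 0.05 against 0.11 pooled. Leaving out 1 array moved the pooled count from 28 (without vector replicate 2) to 94 (without vector replicate 4). A further probe set of Lpl did not pass, nor did those of Angptl4.

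Set against each other at d0 (n = 4 each), EBF1 cells had more Igf2 (log2 fold 3.15 ± 0.35), Postn (2.50 ± 0.17) and Cxcl12 (1.96 ± 0.19) than PPARg cells, and less Ccn2 (-2.14 ± 0.14), Egr1 (-1.68 ± 0.41) and Ankrd1, a nuclear protein of stretched cells (-1.40 ± 0.12, with 2 of 4 EBF1 arrays at the floor). Of 29 cell cycle genes 21 were lower with EBF1 (22 adjusted over the list alone), such as Top2a (-1.04 ± 0.19). Of 20 stress genes 9 were lower (11 list-wise), such as the stress pseudokinase Trib3 (-1.11 ± 0.14). Of 34 matrix genes 6 were higher and 1 lower (10 and 3 list-wise). Among 18 cytokine genes 4 were higher (4 list-wise). Dlk1 was higher (0.65 ± 0.15). Of 27 adipocyte markers the amine oxidase Aoc3 was higher (1.10 ± 0.19) and 3 were lower, with Plin4 at -0.74 ± 0.18 (1 and 4 list-wise). Overall counts were 179 higher and 280 lower probe sets. Of 6 camera calls those for the cell cycle (adjusted p = 1.7e-26) and stress genes (3.6e-10) held, and those for matrix and cytokine genes were lost (adjusted p = 0.20 and 0.060). Blocking on session gave 674 changed probe sets, and the sessions alone gave 319 (186 higher) and 255 (83 higher), with mean log2 marker folds of -0.10 and -0.05 against -0.08 pooled.

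At d2, early in the time course, PPARg and vector cells (n = 4 each) differed in few genes. Plin2, a lipid droplet coat protein (log2 fold 0.93 ± 0.15), Lpl (0.85 ± 0.13) and Postn (0.82 ± 0.17) rose most. The haptoglobin gene Hp (-1.72 ± 0.28), the Wnt antagonist Sfrp1 (-1.42 ± 0.33) and the growth arrest ligand Gas6 (-1.36 ± 0.21) fell most. Among 27 adipocyte markers 4 rose (5 adjusted over the list alone), while Adipoq (0.37 ± 0.23, with 2 of 4 vector arrays at the floor) and Fabp4 (0.42 ± 0.36) did not pass. Of 18 cytokine genes 4 fell (7 list-wise), including the pentraxin Ptx3 (-1.30 ± 0.33), and Top2a fell among cell cycle genes (-1.15 ± 0.19). None of 19 glycolysis genes passed (mean log2 fold -0.14). Only 10 probe sets were higher and 33 lower, 43 against 17 in a fit of these groups alone and 638 with array weights. Camera called 4 lists, the adipocyte markers (adjusted p = 2.8e-08) and the cytokines (4.3e-10) under both correlations, and others such as glycolysis only with the preset correlation (adjusted p = 0.0018, and adjusted p = 0.48 with an estimated correlation). Session as a block gave 92 changed probe sets, and sessions 1 and 2 gave 165 and 14, with mean log2 marker folds of 0.33 and 0.22 against 0.28 pooled. Leaving out 1 array moved the count between 19 (without vector replicate 2) and 82 (without vector replicate 4), and a further probe set of Lpl did not pass.

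EBF1 against vector at d2 (n = 4 each) gave 66 higher and 51 lower probe sets, 142 and 198 with array weights and 14 and 11 in a fit of these groups alone. Ptx3 (log2 fold 2.13 ± 0.33), Hp (1.29 ± 0.28) and the matricellular protein Ccn5 (1.28 ± 0.28) rose most. The polyamine enzyme Sat1 (-1.06 ± 0.18), the lipid droplet dehydrogenase Hsd17b11 (-0.99 ± 0.20) and Sesn1, a p53 target (-0.94 ± 0.15), fell most. Of 19 glycolysis genes 7 rose (15 adjusted over the list alone), such as the glycolytic enzyme Pfkl (0.74 ± 0.19). Agt was the single adipocyte marker of 27 past the test, and it fell (-0.64 ± 0.16; 1 list-wise), while Lpl (0.07 ± 0.13), Adipoq (0.53 ± 0.23) and Fabp4 (0.47 ± 0.36) did not pass. Among 18 cytokine genes 3 rose (3 list-wise), and no cell cycle gene of 29 passed (mean log2 fold 0.16, 1 list-wise). Of 5 camera calls that for glycolysis alone held under both correlations (adjusted p = 2.2e-19), and those for cytokines (adjusted p = 0.0017) and the cell cycle (3.0e-05) were lost (adjusted p = 0.30 and 0.40). Fitted with a session block 227 probe sets changed, and sessions 1 and 2 gave 123 and 98, with mean log2 marker folds of -0.06 and -0.04 against -0.05 pooled. Without vector replicate 4 the count was 72 (29 higher) and without vector replicate 3 it was 73.

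EBF1 cells set against PPARg cells at d2 (n = 4 each) gave 284 higher and 108 lower probe sets. Ptx3 (log2 fold 3.43 ± 0.33), Hp (3.02 ± 0.28) and Igf2 (2.27 ± 0.35) were higher, and Pdk4, a kinase that switches off pyruvate dehydrogenase (-1.58 ± 0.23), the growth factor Ptn (-1.43 ± 0.29) and Agt (-1.32 ± 0.16) were lower. Of the 27 adipocyte markers 6 were lower with EBF1 (8 adjusted over the list alone), with Plin2 at -1.32 ± 0.15 and Lpl at -0.79 ± 0.13. Of 19 glycolysis genes 14 were higher (14 list-wise), with Pfkl at 1.11 ± 0.19. Of 18 cytokine genes 8 were higher (8 list-wise). Also higher were 6 of 29 cell cycle genes (8 list-wise), such as Top2a (1.29 ± 0.19). Of 5 camera calls those for glycolysis (adjusted p = 2.2e-15) and cytokines (3.8e-09) held, and those for adipocyte markers (adjusted p = 4.5e-06) and the cell cycle (6.3e-04) were lost (adjusted p = 0.068 and 0.59). Under a session block 567 probe sets changed, and sessions 1 and 2 gave 452 and 186, with mean log2 marker folds of -0.39 and -0.26 against -0.32 pooled.

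At d4 PPARg against vector (n = 7 each) asks what PPARg2 added to the hormone response in its middle phase. The largest rises were in the calcium binding protein S100a1 (log2 fold 1.36 ± 0.18, with 1 of 7 vector arrays at the floor), Pparg (1.33 ± 0.13), Thrsp, a regulator of lipogenesis (1.33 ± 0.21), the membrane protein Reep6 (1.30 ± 0.18) and Adipoq (1.30 ± 0.17). The largest falls without overlap were in the matricellular protein Thbs2 (-0.65 ± 0.11), the protease inhibitor Timp2 (-0.65 ± 0.14), the ribonuclease Rnase4 (-0.61 ± 0.11), the surface protein Pdpn (-0.59 ± 0.10) and Rassf2 (-0.51 ± 0.08). Among 27 adipocyte markers 14 rose (17 adjusted over the list alone), with Gpd1, which makes glycerol phosphate for triacylglycerol, at 1.11 ± 0.15 and Lpl at 0.64 ± 0.10, while Fabp4 did not pass (0.61 ± 0.27). Of 17 genes of fatty acid and triacylglycerol synthesis 10 rose (10 list-wise), such as the citrate carrier Slc25a1 (1.04 ± 0.12). Of 12 cholesterol synthesis genes 8 rose (9 list-wise), such as Fdps (1.26 ± 0.21). Of 22 fatty acid oxidation genes 18 rose (20 list-wise), such as the peroxisomal thiolase Acaa1a (0.83 ± 0.18). Of 23 citrate cycle and pyruvate dehydrogenase genes 14 rose (18 list-wise), such as Pdhb (0.69 ± 0.15). Of 31 respiratory chain genes 12 rose (22 list-wise), such as cytochrome c, Cycs (0.55 ± 0.14). Of 19 glycolysis genes 9 rose (10 list-wise), such as lactate dehydrogenase, Ldha (0.59 ± 0.11). Of 34 matrix genes 6 fell (11 fell and 1 rose list-wise), with Dcn at -0.43 ± 0.09. Among 18 cytokine genes 5 fell (6 list-wise), such as Saa3 (-0.87 ± 0.23), Ccl2 (-0.70 ± 0.22, with 1 of 7 PPARg arrays at the floor) and Cxcl12 (-0.59 ± 0.15).

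Other groups at d4 with PPARg follow. Of 22 adipogenic transcription factors 3 rose and 1 fell (3 and 2 adjusted over the list alone), with the oxysterol receptor Nr1h3 at 0.57 ± 0.09 and the early regulator Klf4 at -0.73 ± 0.14. Of 20 stress genes 3 rose (3 list-wise), such as the chaperone partner Dnajb9 (0.92 ± 0.13). Of 17 glucocorticoid genes 2 rose and 1 fell (2 and 1 list-wise). Of 19 actin and smooth muscle genes only the calponin Cnn2 fell (-0.47 ± 0.15; 1 list-wise), and no cell cycle gene of 29 and no interferon and antigen presentation gene of 16 passed (0 of each list-wise). None of 9 macrophage, 10 B lineage, 12 skeletal muscle and 3 brown fat genes passed (0 of each list-wise). Of 8 osteoblast and chondrocyte genes only Mgp, the matrix Gla protein, fell (-0.96 ± 0.18; 1 list-wise). By count 434 probe sets were higher, 19 of them at least 2-fold, and 137 lower, 1 of them at least 2-fold. The share of 76.0% higher became 64.1% (403 and 226) with quantile scaling. Camera called 12 of 19 lists, and 7 calls held: adipocyte markers (adjusted p = 3.3e-15), fatty acid and triacylglycerol synthesis (2.4e-13), fatty acid oxidation (1.3e-20), citrate cycle (2.2e-12), cholesterol synthesis (2.0e-14), glycolysis (1.1e-06) and, downwards, cytokines (5.6e-06). The calls for the respiratory chain (adjusted p = 1.5e-12), matrix genes (9.1e-06), actin genes (0.020), interferon genes (0.046) and stress genes (0.0074) were lost (adjusted p = 0.076, 0.060, 0.18, 0.18 and 0.18). A session block gave 856 changed probe sets, and sessions 1, 2 and 3 alone gave 382 (321 higher and 61 lower), 40 (35 and 5) and 255 (114 and 141), with mean log2 marker folds of 0.35, 0.45 and 0.53 against 0.45 pooled. Of the 12 called lists 11, 12 and 12 kept their direction within sessions 1, 2 and 3, and in session 1 alone the actin list (mean log2 fold 0.04), the uncalled glucocorticoid list (0.18), Ccl2 (0.08) and Cnn2 (0.02) turned upwards. Further probe sets of Fdps and Cxcl12 did not pass.

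EBF1 against vector at d4 (n = 7 each) puts the same question for EBF1. Adipoq (log2 fold 2.05 ± 0.17), Gpd1 (2.01 ± 0.15), S100a1 (1.89 ± 0.18, with 1 of 7 vector arrays at the floor), the purine enzyme Impdh1 (1.84 ± 0.12) and the DNA binding protein Nabp1 (1.80 ± 0.17, with 2 of 7 vector arrays at the floor) rose most. The sulfotransferase Sult1a1 (-1.50 ± 0.17), Rnase4 (-1.32 ± 0.11), Igfbp6, which binds insulin-like growth factors (-1.27 ± 0.14), Klf4 (-1.24 ± 0.14) and the lysophosphatidic acid receptor Lpar1 (-1.14 ± 0.15) fell most without overlap. Of 27 adipocyte markers 13 rose and 1 fell (14 and 1 adjusted over the list alone), among them Pparg (1.26 ± 0.13), Fabp4 (1.09 ± 0.27) and Lpl (0.60 ± 0.10). Of 17 genes of fatty acid and triacylglycerol synthesis 10 rose (12 list-wise), such as Thrsp (1.34 ± 0.21). Of 12 cholesterol synthesis genes 9 rose (10 list-wise), such as Fdps (1.45 ± 0.21). Of 22 fatty acid oxidation genes 18 rose and 1 fell (18 and 1 list-wise), such as Etfdh (1.21 ± 0.14). Of 23 citrate cycle genes 17 rose and 1 fell (18 and 2 list-wise), such as Sucla2 (1.11 ± 0.17). Of 31 respiratory chain genes 25 rose (26 list-wise), such as Cycs (1.09 ± 0.14). Of 34 matrix genes 14 fell and 1 rose (19 and 1 list-wise), with Timp2 at -0.97 ± 0.14 and Postn at 0.75 ± 0.13. Of 17 glucocorticoid genes 10 fell and 1 rose (11 and 2 list-wise), such as the kinase Sgk1 (-0.89 ± 0.15) and Ddit4, an inhibitor of mTOR (-0.68 ± 0.10).

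Further groups changed at d4 with EBF1. Among 29 cell cycle genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with Mki67 at 0.68 ± 0.15 and Top2a at -0.42 ± 0.14. Of 22 adipogenic transcription factors 2 rose and 3 fell (2 and 3 list-wise), with the early regulators Klf5 at -1.03 ± 0.14 and Cebpd at -0.39 ± 0.14; the mean and the test were negative and the median (0.01) was not. Of 20 stress genes 7 rose and 1 fell (7 and 1 list-wise), such as Psat1 of serine synthesis (1.04 ± 0.14). Of 19 glycolysis genes 7 rose and 1 fell (7 and 1 list-wise). Of 19 actin genes 5 fell (5 list-wise), with Cnn2 at -0.69 ± 0.15. Of 16 interferon genes 4 fell (4 list-wise), with B2m of antigen presentation at -0.42 ± 0.10. Of 18 cytokine genes 4 fell and 1 rose (4 and 1 list-wise), with the acute phase inhibitor Serpina3n at -0.61 ± 0.11 and Hp at 0.58 ± 0.21. No macrophage gene of 9, B lineage gene of 10, skeletal muscle gene of 12 or brown fat gene of 3 passed (0 of each list-wise). Of 8 osteoblast and chondrocyte genes Mgp fell (-1.21 ± 0.18; 1 list-wise), with a median of 0.09 against a mean of -0.13 and a downward test. Of all probe sets 837 were higher, 42 of them at least 2-fold, and 603 lower, 18 of them at least 2-fold. The share of 58.1% higher became 46.6% (723 and 829) with quantile scaling. Camera called 13 of 19 lists, and 6 calls held: adipocyte markers (adjusted p = 3.9e-06), fatty acid and triacylglycerol synthesis (2.5e-06), respiratory chain (1.4e-16), matrix (3.3e-08), glucocorticoid response (1.3e-06) and cholesterol synthesis (8.0e-07). The calls for fatty acid oxidation (adjusted p = 5.6e-11), citrate cycle (2.1e-11), actin (0.012), cell cycle (0.0026), interferon (0.032), glycolysis (0.012) and stress genes (0.021) were lost (adjusted p = 0.055, 0.055, 0.18, 0.28, 0.18, 0.28 and 0.28). A fit with sessions as blocks gave 1785 changed probe sets, and sessions 1, 2 and 3 gave 1060 (870 higher and 190 lower), 195 (126 and 69) and 911 (320 and 591), with mean log2 marker folds of 0.43, 0.48 and 0.44 against 0.45 pooled. All 13 called lists kept their direction in each session, Hp turned downwards in session 3 alone (log2 fold -0.18), and a further probe set of Fdps did not pass.

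EBF1 cells against PPARg cells at d4 (n = 7 each) differed in 150 higher and 303 lower probe sets. The share of 33.1% higher became 55.3% (360 and 291) with each array's 20th percentile as a covariate and 68.8% (1589 and 720) with array weights. Impdh1 (log2 fold 1.42 ± 0.12), Ccl2 (1.06 ± 0.22, with 1 of 7 PPARg arrays at the floor) and Gpd1 (0.90 ± 0.15) were higher with EBF1, and Cyp2f2, a cytochrome P450 (-1.72 ± 0.16), Sult1a1 (-1.48 ± 0.17) and Plin4 (-1.27 ± 0.13) were lower. Adipoq was higher (0.75 ± 0.17), and Pparg (-0.07 ± 0.13), Lpl (-0.04 ± 0.10) and Fabp4 (0.48 ± 0.27) did not pass. Among 27 adipocyte markers 2 were higher and 5 lower (3 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.39), with a median of 0.03 against a mean of -0.01 and a downward test. Of 17 glucocorticoid genes 8 were lower with EBF1 (11 lower and 1 higher list-wise), such as Ddit4 (-0.89 ± 0.10). Of 31 respiratory chain genes 6 were higher (12 list-wise), such as Cycs (0.54 ± 0.14). Camera called 5 lists, the glucocorticoid list under both correlations (adjusted p = 1.4e-09) and others such as the respiratory chain only with the preset correlation (adjusted p = 2.4e-06, and adjusted p = 0.62 with an estimated correlation). Taking session as a block gave 694 changed probe sets, and sessions 1, 2 and 3 gave 264, 24 and 99, with mean log2 marker folds of 0.08, 0.04 and -0.09 against -0.01 pooled.

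At d10 PPARg against vector (n = 3 each) asks about the late state with PPARg2. Ephx2, an epoxide hydrolase (log2 fold 3.66 ± 0.26), S100a1 (3.55 ± 0.28, with 1 of 3 vector arrays at the floor), the carbonic anhydrase Car3 (3.43 ± 0.19), Reep6 (3.42 ± 0.27) and Adipoq (3.15 ± 0.26) rose most. Cxcl5 (-2.47 ± 0.17, with 1 of 3 PPARg arrays at the floor), Acta2 (-1.94 ± 0.47), the surface protein Emb (-1.81 ± 0.20), the lipid phosphatase Plpp1 (-1.69 ± 0.24) and the growth factor Fgf7 (-1.68 ± 0.21) fell most. Of 27 adipocyte markers 20 rose (22 adjusted over the list alone), such as the lipid droplet protein Cidec (3.11 ± 0.20), Fabp4 (2.75 ± 0.42, with 1 of 3 vector arrays at the floor) and Lpl (1.42 ± 0.15), and Pparg rose at least 3.62-fold. Of 17 genes of fatty acid and triacylglycerol synthesis 14 rose (14 list-wise), such as Gpd1 (2.89 ± 0.23) and the desaturase Scd1 (2.68 ± 0.21). Of 12 cholesterol synthesis genes 10 rose (11 list-wise), such as Fdps (2.73 ± 0.32). Of 22 fatty acid oxidation genes 21 rose (21 list-wise), such as the thiolase Acaa2 (1.98 ± 0.16). Of 23 citrate cycle genes 19 rose (21 list-wise), such as the carboxylase Pcx (2.40 ± 0.17). Of 31 respiratory chain genes 25 rose (26 list-wise), such as Cycs (2.09 ± 0.22). Of 34 matrix genes 20 fell (23 fell and 1 rose list-wise), such as fibulin, Fbln2 (-1.53 ± 0.21). Of 19 actin and smooth muscle genes 11 fell (12 list-wise), such as the tropomyosin Tpm1 (-1.49 ± 0.20). Among 18 cytokine genes 8 fell (8 list-wise), such as Ccl2 (-1.63 ± 0.33).

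Among regulators at d10 with PPARg, 5 of 22 adipogenic transcription factors rose and 5 fell (5 and 5 adjusted over the list alone), with Nr1h3 at 1.75 ± 0.14, Cebpb at 0.91 ± 0.22, Cebpd at -1.22 ± 0.21 and Id2, an inhibitor of helix-loop-helix factors, at -1.52 ± 0.28. Dlk1 fell (-0.71 ± 0.17). Of 17 glucocorticoid genes 2 rose and 3 fell (2 and 3 list-wise), with Angptl4 at 1.22 ± 0.17. Of 16 interferon genes 1 rose and 4 fell (1 and 4 list-wise), with Ifitm3 at -1.09 ± 0.16. Of 19 glycolysis genes 4 rose and 4 fell (4 and 5 list-wise), with aldolase, Aldoa, at 1.08 ± 0.10 and the stress gene Ndrg1 at -1.11 ± 0.20. Of 20 stress genes 4 rose and 5 fell (4 and 5 list-wise), with Dnajb9 at 1.32 ± 0.20 and the heat shock gene Hspa1b at -0.82 ± 0.18. Of 29 cell cycle genes 1 fell, Mcm3 of the replicative helicase (-0.43 ± 0.13; 0 list-wise). No macrophage gene of 9 or B lineage gene of 10 passed (0 of each list-wise). Of 12 skeletal muscle genes 1 fell, Myod1 (-0.40 ± 0.14; 0 list-wise). Of 3 brown fat genes 1 rose, the muscle form of a respiratory subunit, Cox8b (1.73 ± 0.21; 1 list-wise). Of 8 osteoblast and chondrocyte genes 1 rose and 2 fell (1 and 2 list-wise), with Bmp4 at 0.41 ± 0.13, Mgp at -1.67 ± 0.27 and Ogn at -1.48 ± 0.28, and with a median of 0.10 against a mean of -0.28 and a downward test. The counts were 716 higher probe sets, 224 of them at least 2-fold, and 1082 lower, 168 of them at least 2-fold. Camera called 9 of 19 lists: adipocyte markers (adjusted p = 7.9e-30), fatty acid and triacylglycerol synthesis (5.3e-20), fatty acid oxidation (4.9e-24), citrate cycle (5.2e-16), respiratory chain (7.6e-20) and cholesterol synthesis (1.4e-13) upwards, and matrix (1.7e-09), actin (1.3e-06) and cytokine genes (2.8e-04) downwards. All held except the cytokine genes (adjusted p = 0.052 with an estimated correlation). Session 3, which held all d10 arrays, gave 1811 changed probe sets alone, and a session block gave 2091, each with the 9 lists called and with the mean of 1.63 for the adipocyte markers unchanged. Further probe sets of Scd1, Cox8b, Fdps, Angptl4 and Mcm3 did not pass.

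EBF1 against vector at d10 (n = 2 and 3) follows. S100a1 (log2 fold 4.24 ± 0.31, with 1 of 3 vector arrays at the floor), Ephx2 (3.65 ± 0.29), Reep6 (3.46 ± 0.30), Cidec (3.41 ± 0.22) and Adipoq (3.41 ± 0.30) rose most. Mgp (-1.78 ± 0.31, with 1 of 2 EBF1 arrays at the floor), the carboxypeptidase inhibitor Lxn (-1.55 ± 0.21), the angiotensin receptor Agtr2 (-1.44 ± 0.41), Crabp1 (-1.43 ± 0.20) and the surface protein Cd24a (-1.38 ± 0.17) fell most. Among 27 adipocyte markers 20 rose (21 adjusted over the list alone), such as Fabp4 (3.34 ± 0.47, with 1 of 3 vector arrays at the floor) and Lpl (1.80 ± 0.17), and Pparg rose at least 4.02-fold. Of 17 genes of fatty acid and triacylglycerol synthesis 14 rose (14 list-wise), such as Gpd1 (3.37 ± 0.25) and Scd1 (2.82 ± 0.24). Of 12 cholesterol synthesis genes 10 rose (12 list-wise), such as Fdps (2.72 ± 0.36). Of 22 fatty acid oxidation genes 21 rose (21 list-wise), such as Hadhb (2.76 ± 0.23). Of 23 citrate cycle genes 19 rose (20 list-wise), counting the inhibitory kinase Pdk4 (2.69 ± 0.29). Of 31 respiratory chain genes 26 rose (28 list-wise), such as Cycs (2.75 ± 0.25). Of 34 matrix genes 9 fell (10 list-wise), such as Thbs2 (-0.92 ± 0.20). Of 19 actin genes 8 fell (9 list-wise), such as Cnn2 (-1.07 ± 0.25). Among 29 cell cycle genes 7 fell (8 list-wise), such as Top2a (-0.75 ± 0.25).

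Regulators and other groups at d10 with EBF1 follow. Of 22 adipogenic transcription factors 5 rose and 2 fell (6 and 3 adjusted over the list alone), with Nr1h3 at 2.00 ± 0.16 and Cebpb at 1.41 ± 0.25, while Cebpd (-0.63 ± 0.24) and Dlk1 (-0.18 ± 0.19) did not pass. Of 17 glucocorticoid genes 4 rose and 1 fell (4 and 3 list-wise), with the phosphatase Dusp1 at 1.19 ± 0.28, a median of -0.07, a mean of 0.23 and an upward test. Of 20 stress genes 3 rose and 1 fell (3 and 1 list-wise), with Dnajb9 at 1.65 ± 0.23, a median of -0.04, a mean of 0.12 and an upward test. Of 19 glycolysis genes 7 rose and 3 fell (8 and 3 list-wise), with Aldoa at 1.35 ± 0.11. Of 18 cytokine genes 5 fell (5 list-wise), with Cxcl5 at -0.85 ± 0.19. Of 16 interferon genes 1 rose and 2 fell (1 and 2 list-wise). No macrophage gene of 9, B lineage gene of 10 or skeletal muscle gene of 12 passed (0 of each list-wise), and the B lineage list had a median of 0.01 and a mean of 0.03 with a downward test. Among 3 brown fat genes Cox8b (1.52 ± 0.24) and Cidea (1.08 ± 0.18) rose (3 list-wise). Of 8 osteoblast and chondrocyte genes 1 rose and 2 fell (1 and 2 list-wise), with a median of 0.22 against a mean of -0.13 and a downward test. Higher probe sets numbered 799, of which 338 were at least 2-fold, and lower ones 594, of which 37 were at least 2-fold. The share of 57.4% higher became 47.5% (755 and 834) with quantile scaling. Camera called 11 of 19 lists, and the 7 that held were adipocyte markers (adjusted p = 1.3e-28), fatty acid and triacylglycerol synthesis (1.9e-21), fatty acid oxidation (7.2e-35), citrate cycle (1.4e-24), respiratory chain (6.8e-27), cholesterol synthesis (7.4e-14) and, downwards, actin genes (7.3e-05). The calls for matrix (adjusted p = 6.7e-06), cell cycle (8.7e-04), cytokine (0.014) and glycolysis genes (0.036) were lost (adjusted p = 0.052, 0.29, 0.23 and 0.40). A fit of session 3 alone gave 1399 changed probe sets and a session block gave 1717, each with the 11 lists called. Here too the folds cannot change, as all d10 arrays lie in session 3. Without EBF1 replicate 1 of d10, which left 1 EBF1 array, the count was 614, and further probe sets of Scd1, Fdps, Cox8b and Angptl4 did not pass.

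EBF1 against PPARg at d10 (n = 2 and 3) asks how the late states differ. Pdk4 (log2 fold 2.06 ± 0.29), Cxcl5 (1.62 ± 0.19, with 1 of 3 PPARg arrays at the floor) and 4931406C07Rik (1.48 ± 0.29) were higher with EBF1, and Cyp2f2 (-2.14 ± 0.27), Car3 (-1.86 ± 0.21) and the apolipoprotein Apoc1 (-1.34 ± 0.30) were lower. Adipoq (0.26 ± 0.30), Lpl (0.38 ± 0.17), Fabp4 (0.59 ± 0.47) and Pparg (0.15 ± 0.22) did not pass. Of 27 adipocyte markers 1 was higher and 3 lower (2 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.77), with a median of 0.15 and a mean of 0.02 against a downward test. Of 22 fatty acid oxidation genes 6 were higher with EBF1 (11 list-wise), such as Hadhb (1.04 ± 0.23). Of 23 citrate cycle genes 2 were higher (6 list-wise), such as Idh3a (0.58 ± 0.15), and none of 31 respiratory chain or 29 cell cycle genes passed (0 of each list-wise). Camera called 7 lists, these 4 among them (adjusted p = 6.7e-16, 4.0e-09, 3.4e-07 and, downwards, 4.0e-09), and each of the 7 calls was lost (for these 4 adjusted p = 0.11, 0.24, 0.31 and 0.14). The comparison gave 76 higher and 25 lower probe sets, a share of 75.2% higher that became 52.6% (51 and 46) with quantile scaling. A session block gave 176 and session 3 alone 62 changed probe sets, the count was 12 without EBF1 replicate 1, 54 without PPARg replicate 1 and 57 without PPARg replicate 2, and 0 passed in a limma fit of the 2 groups alone, where 470 had an unadjusted p under 0.05.

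Within PPARg cells, d10 (n = 3) against d0 (n = 4) gave 1022 higher and 1428 lower probe sets. Adipoq rose at least 118-fold and Ephx2 at least 51.2-fold, as all 4 arrays of d0 were at the floor, and Prxl2a, a redox protein, rose by a log2 fold of 5.02 ± 0.27. The chromatin protein Hmga2 (-3.70 ± 0.33) and the annexin Anxa3 (-3.02 ± 0.17, with 2 of 3 arrays of d10 at the floor) fell, as did Ccn2, by at least 11.2-fold. Of the 27 adipocyte markers 21 rose (22 adjusted over the list alone) and of 22 fatty acid oxidation genes 21 rose (21 rose and 1 fell list-wise), while 23 of 29 cell cycle genes fell (24 list-wise), with Birc5 at -1.93 ± 0.15. Of 12 cholesterol synthesis genes 7 fell and 1 rose (7 and 1 list-wise), with Fdft1 at -1.44 ± 0.13. Of 10 camera calls 5 held, such as those for adipocyte markers (adjusted p = 5.0e-28), fatty acid oxidation (1.2e-24) and the cell cycle (5.6e-13), and that for cholesterol synthesis (adjusted p = 0.0088) was lost (adjusted p = 0.24). Tied through d4 by a session block, 2150 probe sets changed and the mean log2 fold of the adipocyte markers was 2.10, as without it.

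Within EBF1 cells, d10 (n = 2) against d0 (n = 4) gave 1114 higher and 991 lower probe sets, a share of 52.9% higher that became 45.0% (1068 and 1303) with quantile scaling. Adipoq (log2 fold 7.13 ± 0.28, with 3 of 4 arrays of d0 at the floor) and Reep6 (5.04 ± 0.28) rose, as did Ephx2, by at least 50.7-fold, and Hmga2 (-3.06 ± 0.38), Mgp (-2.55 ± 0.29, with 1 of 2 arrays of d10 at the floor) and Anxa3 (-2.41 ± 0.19) fell. Of 27 adipocyte markers 21 rose (21 adjusted over the list alone) and of 22 fatty acid oxidation genes 21 rose (21 rose and 1 fell list-wise), such as Acadm (3.54 ± 0.15). Of 29 cell cycle genes 16 fell (17 list-wise), with Birc5 at -1.37 ± 0.17. Of 12 cholesterol synthesis genes 4 fell and 1 rose (5 and 1 list-wise), with Fdft1 at -1.14 ± 0.15. Of 6 camera calls 5 held, such as those for adipocyte (adjusted p = 1.8e-27) and oxidation genes (2.8e-32), that for the cell cycle (adjusted p = 8.5e-07) was lost (adjusted p = 0.13), and cholesterol synthesis was not called (adjusted p = 0.17). Through a session block 1729 probe sets changed, with a mean log2 fold of the adipocyte markers of 2.19, and without EBF1 replicate 1 of d10 the count was 1216.

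The change of each insert's difference from vector between d0 and d10 asks which insert effects came only with time. For PPARg the signed difference moved upwards in 392 probe sets and downwards in 544. Ephx2 (3.66 ± 0.34), S100a1 (3.55 ± 0.37) and Car3 (3.45 ± 0.25) led upwards, and Cxcl5 (-2.47 ± 0.22), Ccl2 (-2.41 ± 0.44) and Egr1 (-2.35 ± 0.63) downwards. For EBF1 it moved upwards in 636 and downwards in 329. S100a1 (4.24 ± 0.39), Ephx2 (3.65 ± 0.37) and Reep6 (3.56 ± 0.38) led upwards, and Igf2 (-2.33 ± 0.58), Agtr2 (-2.07 ± 0.52) and Lxn (-1.82 ± 0.26) downwards. Under a session block 1255 and 1258 probe sets changed, and without EBF1 replicate 1 of d10 the EBF1 count was 468.

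How alike the EBF1 and PPARg effects were on each day was measured over 5761 genes, which are not independent replicates. Pearson's r between the log2 folds over vector was 0.18 at d0, -0.23 at d2, 0.69 at d4 and 0.91 at d10, and Spearman's rho was 0.29, -0.18, 0.57 and 0.86. With array weights r was 0.59 at d0 and 0.30 at d2. Leaving out 1 array moved r from 0.05 (without EBF1 replicate 2) to 0.51 (without vector replicate 4) at d0 and from -0.34 (without EBF1 replicate 4) to 0.16 (without vector replicate 4) at d2. The jackknife SE of r over arrays was 0.38, 0.45, 0.14 and 0.067. Both folds share the vector arrays, and draws of residuals without any effect gave a mean r of 0.47, 0.50, 0.47 and 0.40, with a highest r of 0.93, 0.92, 0.94 and 0.91 over 100 draws. In covariance, the measure less swayed by such sharing, the data gave 0.0064 at d0, -0.0067 at d2, 0.035 at d4 and 0.215 at d10, against simulated means of 0.0124, 0.0130, 0.0069 and 0.0137 and highest draws of 0.077, 0.061, 0.044 and 0.064. Only at d10 was the covariance above every draw. With the vector arrays split so that each insert had its own controls, r averaged -0.13 at d0, -0.41 at d2, 0.48 at d4 and 0.79 at d10, where either side had 1 or 2 vector arrays, and at its lowest it was -0.39, -0.70, 0.02 and 0.68. At d10 468 of the 553 genes higher with PPARg and the 609 higher with EBF1 were shared (58.5 expected if independent), as were 402 of 834 and 455 lower genes (65.9 expected), and none went opposite ways. At d4 283 of 343 and 654 higher genes (38.9 expected) and 91 of 114 and 470 lower genes (9.30 expected) were shared, and 2 went opposite ways. At d0 the inserts shared 3 higher and 3 lower genes with 8 opposite, and at d2 they shared 0 higher and 1 lower with 6 opposite. Shared controls add to these overlaps too.

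**Figure D3:**
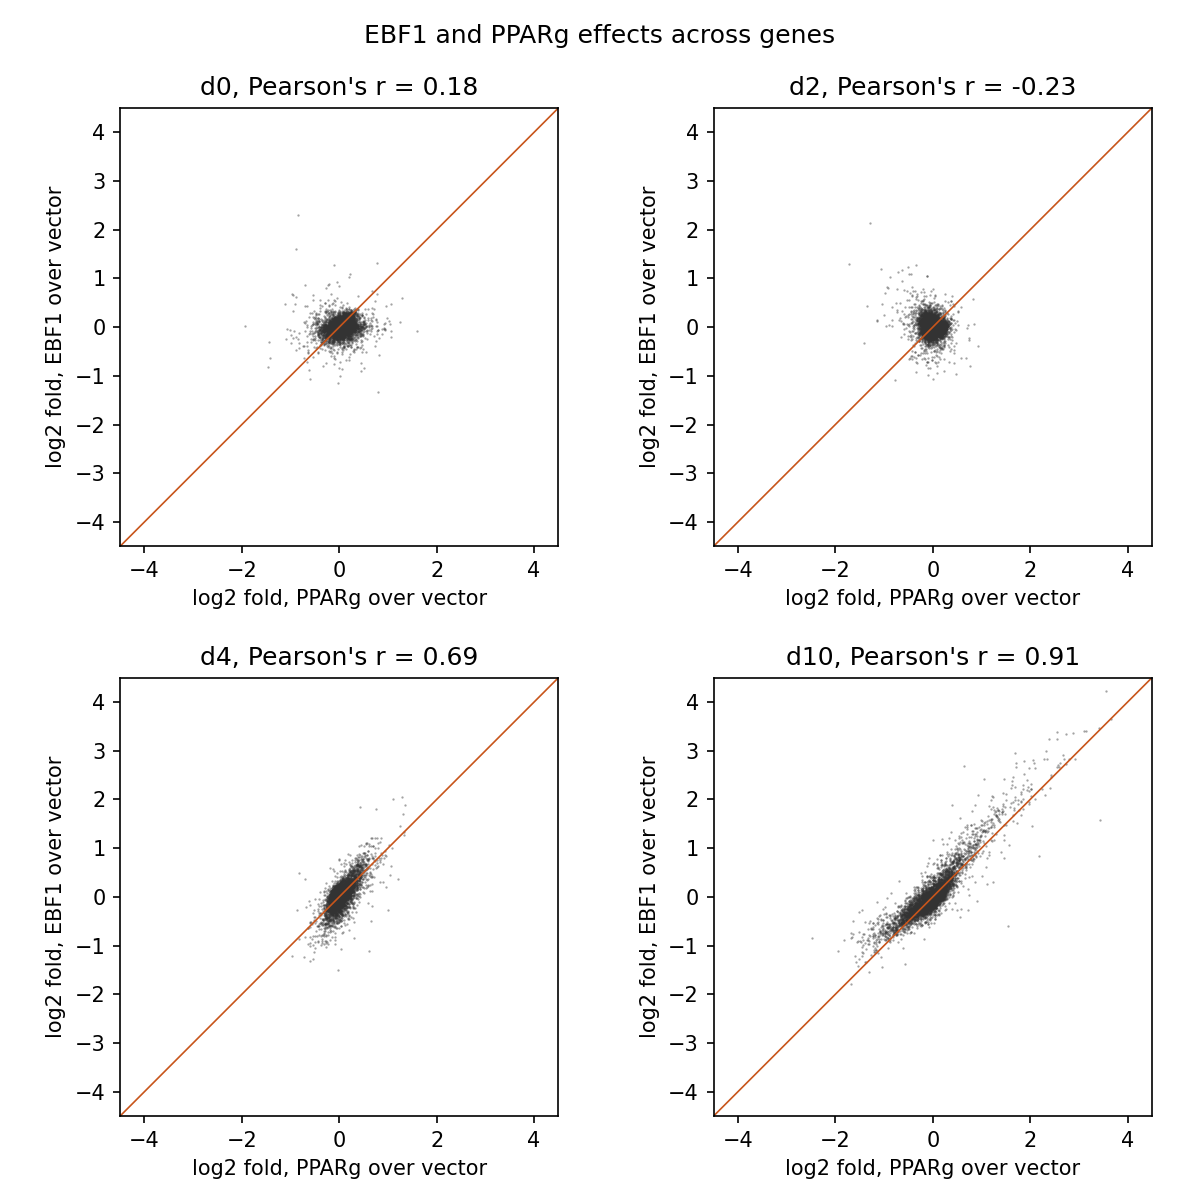
Log2 fold of EBF1 over vector against log2 fold of PPARg over vector for 5761 genes at d0, d2, d4 and d10, each point a gene, with the line of equality. Pearson's r was 0.18, -0.23, 0.69 and 0.91.

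**Figure D4:**
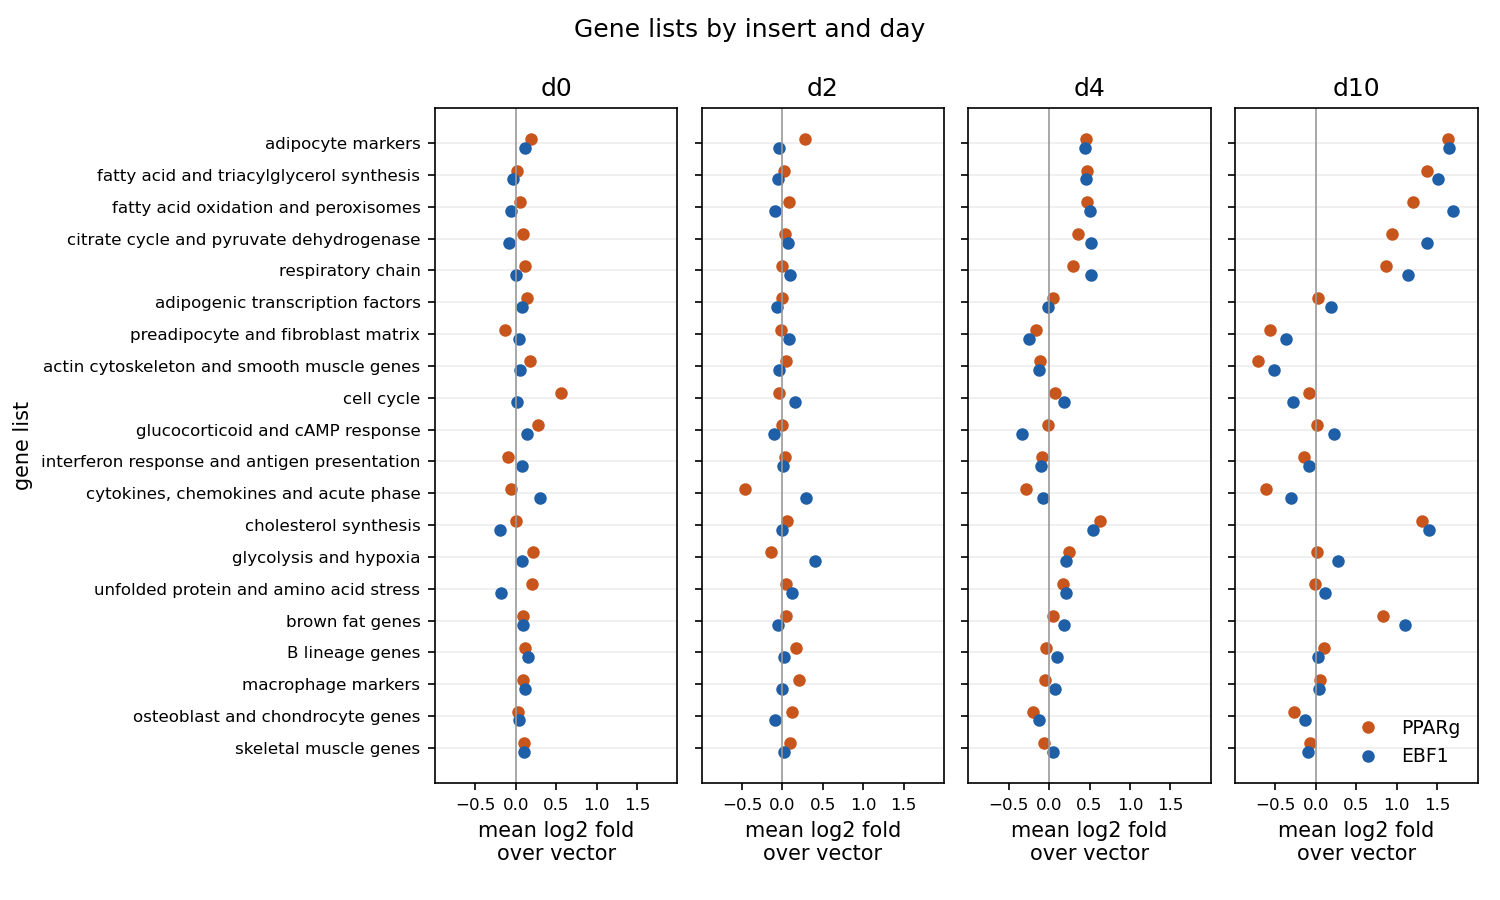
Mean log2 fold over vector of the tested genes of 19 lists and the 3 brown fat genes, by insert and day. Adipocyte markers averaged 0.45 with either insert at d4, and 1.63 with PPARg and 1.65 with EBF1 at d10.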

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

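The outlier search, the differences between d10 and d0 effects and the regrouping of arrays were set before the data were examined, and the tests of the 3 patterns weighed below were chosen only after the result was seen. For 11 genes and the adipocyte score in each of 9 groups of at least 4 arrays, 108 sets of values, the gap between the most distant array and its neighbour was divided by the range of the group. It passed Dixon's limit in 7 sets, where chance alone gives about 1 in 20 groups, or 5.4. Adipoq gave 3 of these where the group lay at or near the floor: replicate 4 of vector at d0 and replicate 3 of EBF1 at d0 (1 in each, the other 3 arrays at the floor) and replicate 4 of vector at d2 (0.99, with 2 arrays at the floor). Ebf1 on replicate 3 of vector at d0 gave 0.92. Replicate 7 of EBF1 at d4 was low for Adipoq (0.682), Lpl (0.582) and the adipocyte score (0.672), 3 measures that are not independent. Without that array the score difference from vector at d4 was 0.43 in place of 0.39. No biological explanation was tested for these arrays.

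The insert effects differed between days by a test of the difference itself, in 936 probe sets for PPARg and 965 for EBF1. Regrouping the arrays within each day cannot decide on chance for the PPARg count, as d10 has only 10 splits: 10 of 100 joint splits gave as many (highest other 1839 against 936), and all 10 kept the real d10 groups. The EBF1 count was not put to this, as d10 had 2 EBF1 arrays. The d0 and d10 arrays were processed in different sessions. With session as a block the counts were 1255 and 1258.

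The first pattern weighed was that the EBF1 and PPARg effects moved together at d10, with r = 0.91 and a covariance of 0.215. Noise of shared vector arrays was argued against: with separate ones the lowest covariance over the divisions was 0.175. So was array-wide spread in low intensities: r was 0.911 with each array's 20th percentile as a covariate. A shift common to all vector arrays of d10, which no division removes, and a common late response to both inserts stay open as hypotheses.

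The second was that vector cells had a lower adipocyte score at d10 than at d4, by 0.54 over all arrays (exact permutation p = 0.0083). The processing session was argued against as the whole cause, since within session 3 every d4 array lay above every d10 array and the difference was 0.517 (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). After the trend with the arrays' 20th percentile was removed it was 0.541. A candidate explanation is that vector cells lost part of their early change by d10, and it was not tested.

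The third was that PPARg cells had a higher score than EBF1 cells at d2, by 0.30, whereas the difference was 0.06 at d0 and both stood alike at d4 and d10. The difference was 0.357 in session 1 and 0.251 in session 2, without overlap in either, and 0.272 after the trend with the 20th percentile was removed, which argues against session and array-wide spread as the whole cause. Whether PPARg2 acts on marker genes sooner than EBF1 stays open: at d0 Lpl and Angptl4 stood above vector with EBF1 (0.74 ± 0.13 and 0.60 ± 0.15) and with PPARg (0.68 ± 0.13 and 1.29 ± 0.15), as did Plin4 with PPARg alone (0.77 ± 0.18), the permutation test at d2 did not pass after adjustment (adjusted p = 0.086), and the change of the difference between days was not tested.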

How the results depend on the processing

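The fit with each array's 20th percentile as a covariate and the weights estimated gene by gene were chosen only after the data were seen, and the other alternatives before. Counts below are of changed probe sets. For the moved counts the cause was not tested.

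With the higher floor, no filter and the strict filter all 19 counts stayed within 1.5 times their value, and with quantile normalization 18 did, while EBF1 against vector at d2 gave 177. Quantile normalization turned the majority from higher to lower in PPARg against vector at d0, EBF1 against vector at d4 and d10 and EBF1 d10 against d0. Array weights turned it in EBF1 against vector at d0 and d2 and EBF1 against PPARg at d4, and the covariate in EBF1 against vector at d0, EBF1 against PPARg at d4 and EBF1 d10 against d0. A single session turned it in both inserts against vector at d0 and d4, EBF1 against PPARg at d0 and vector d4 against d0. A fit of only the groups compared turned it in EBF1 against vector at d0 (19 higher and 12 lower) and vector d4 against d0 (660 and 649). Of 272 named gene folds past the test 264 stayed past it at the higher floor and 265 without a filter, as did all of the 265 with a value under the strict filter and 268 of 271 under quantile normalization. None of these folds turned, but Pparg in vector cells at d4 lost its call at the higher floor, which puts both groups at the floor. Of 96 list calls 95, 91, 96 and 94 stayed under quantile normalization, the higher floor, no filter and the strict filter, and 53 with an estimated correlation in camera.

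A fit of only the groups compared has fewer arrays to estimate the spread. It gave 115 for PPARg against vector at d0 and 17 at d2, 31, 25 and 855 for EBF1 against vector at d0, d2 and d10, 636 and 0 for EBF1 against PPARg at d2 and d10, and 1049 and 658 for vector d2 and d10 against d0. Beside the 0 of this limma fit stand 470 with an unadjusted p under 0.05. Of the 272 named folds 236 stayed past the test.

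Array weights raised most counts. They gave 4866, 638 and 4144 for PPARg against vector at d0, d2 and d10, 2801, 340 and 2375 for EBF1 against vector at d0, d2 and d4, 1250, 1039, 2309 and 324 for EBF1 against PPARg at d0, d2, d4 and d10, 3143, 3633 and 2418 for vector d2, d4 and d10 against d0, 5435 for PPARg d10 against d0, and 2246 for the difference of PPARg effects. Weights estimated gene by gene gave 4328, 440 and 3644, then 2353, 264 and 2294, then 1054, 979, 1871 and 290, then 3046, 3400 and 2216, then 4452, and 1890 in the same order. The r of d0 was 0.595 and 0.589 with these weights, and that of d2 turned positive, 0.299 and 0.228. Of the 272 named folds 268 and 268 stayed past the test.

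Replicate numbers were not taken as pairs, since 6 of 18 numbers on a day had every correlation of residuals over 0.1, correlations ran from -0.58 to 0.78, and 25 of 53 arrays lay closest to their own number. At d2 pairing is not excluded, as 3 of 4 numbers passed, the other had 0.07 at its lowest, and 10 of 12 arrays lay closest to their own number. With replicate number as a block, the counts were 468, 98 and 922 for PPARg against vector at d0, d2 and d4, 114 and 238 for EBF1 against vector at d0 and d2, and 754, 615, 764 and 246 for EBF1 against PPARg at d0, d2, d4 and d10. The score differences from vector at d4 were unchanged by the block (0.385 for PPARg and 0.388 for EBF1), but swaps within pairs allow fewer permutations and the adjusted p was 0.094 for each. Under the other alternatives of these score tests, leaving out arrays included, it ran from 0.0035 to 0.017.

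Session as a block gave 442 and 92 for PPARg against vector at d0 and d2, 102 and 227 for EBF1 against vector at d0 and d2, 694 and 176 for EBF1 against PPARg at d4 and d10, and 711 for vector d10 against d0. Single sessions hold 2 or 3 arrays per group. Session 1 gave 527 and 165 for PPARg against vector at d0 and d2, 119 for EBF1 against vector at d0 and 264 for EBF1 against PPARg at d4. Session 2 gave 125, 14 and 40 for PPARg against vector at d0, d2 and d4, 19 and 195 for EBF1 against vector at d0 and d4, 255, 186 and 24 for EBF1 against PPARg at d0, d2 and d4, and 722 and 645 for vector d2 and d4 against d0. Session 3 gave 255 and 911 for PPARg and EBF1 against vector at d4, and 99 and 62 for EBF1 against PPARg at d4 and d10. In session 1 Ccl2 (0.082), Cnn2 (0.017), the actin list (mean log2 fold 0.038) and the glucocorticoid list (0.18) turned upwards in PPARg against vector at d4. In session 3 Hp turned downwards (-0.18) in EBF1 against vector at d4. All 272 named folds stayed past the test with the session block, and 136 of 153, 113 of 153 and 124 of 147 within sessions 1, 2 and 3. The covariate gave 508 for PPARg against vector at d0, 224 for EBF1 against vector at d2, 752 and 199 for EBF1 against PPARg at d0 and d10 and 1917 for vector d10 against d0.

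Leaving out 1 array at a time moved 7 of 19 counts by more than 1.5 times. EBF1 against vector at d0 ran from 28 to 94 (without vector replicates 1, 2 and 4 it was 31, 28 and 94, and without EBF1 replicates 3 and 4 it was 35 and 32). PPARg against vector at d2 ran from 19 to 82 (23, 19 and 82 without vector replicates 1, 2 and 4, and 27 and 23 without PPARg replicates 2 and 4). EBF1 against vector at d2 ran from 72 to 130 (73 and 72 without vector replicates 3 and 4, and 76 without EBF1 replicate 2). EBF1 against PPARg at d10 ran from 12 to 119 (54 and 57 without PPARg replicates 1 and 2). The lowest values came without EBF1 replicate 1 of d10 in that count (12), in EBF1 against vector at d10 (614, highest 1471), in EBF1 d10 against d0 (1216, highest 2094) and in the difference of EBF1 effects (468, highest 973). There the lone EBF1 array is assumed to vary like the other groups. The r of d2 ran from -0.34 to 0.16, positive only without vector replicate 4, and that of d0 from 0.05 (EBF1 replicate 2) to 0.51 (vector replicate 4). The majority turned in PPARg against vector at d0 without vector replicate 4 or PPARg replicate 3, EBF1 against vector at d0 without vector replicate 1, 2 or 3 or EBF1 replicate 2, EBF1 against vector at d2 without vector replicate 4 (40.3% higher), vector d4 against d0 without replicate 1 or 2 of d0 or 1 of d4, and the difference of PPARg effects without vector replicate 4 of d0 (52.3%) or PPARg replicate 1 of d10 (51.3%). Of 2455 calls of named folds over these fits 2347 were kept and none turned. Low signal limits what can be read: 20% of all values lay below the floor, and folds against groups there are lower limits.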

Other observations

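The hypothesis and the splits of the arrays were set before the result was seen, and the splits within sessions were chosen only after it. The hypothesis was that the probe sets that PPARg raised before stimulation are among those that EBF1 raised by d10. Of 159 such probe sets 26 were higher in EBF1 cells at d10, against 16.7 if independent, 22 were lower, against 12.4, and their median log2 fold was -0.13. The hypothesis asked for at least 2 times the independent number and a median above 0, and the result was negative. PPARg at d10 missed this rule too (29 higher against 14.9, median -0.02), so the result is not particular to EBF1.

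The arrays of each comparison with at least 3 per group were split otherwise into the same sizes, without regard to session or replicate number. Chance could be excluded for PPARg against vector at d0 (274, highest other split 26 of 35 splits) and at d4 (571, highest other 1458, where 3 of 100 splits gave as many), for EBF1 against vector at d2 (117 and 12) and d4 (1440 and 1330), for EBF1 against PPARg at d0 (459 and 279) and d2 (392 and 0), for vector d4 (1840 and 1411) and d10 (1172 and 1028) against d0, and for PPARg d10 against d0 (2450 and 1839). The share was at or above 0.05 for PPARg against vector at d2 (43 and 75), EBF1 against vector at d0 (62 and 1102), EBF1 against PPARg at d4 (453 and 1800, with 5 of 100 splits) and vector d2 against d0 (1635 and 2233). These 4 were also split within each session, with session as a block. The share was then under 0.05 for EBF1 against PPARg at d4 (694, highest other 416, 1 of 100 splits), with the same limits. The other 3 had 18 splits, too few for a share under 0.05: PPARg at d2 gave 92 (highest other 28) and EBF1 at d0 102 (highest other 1), each the only 1 as large, and vector d2 1944 (highest other 2119, 2 as large). In all 4 comparisons every called list kept its direction in each session. PPARg against vector at d10 (1798 and 41) had 10 splits, too few for a share under 0.05. In EBF1 against vector at d0 the split that follows the processing sessions called 627. There and in both d4 comparisons where a split called more than 2 times the real count, the arrays have a structure other than their groups.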
